A study of Mus musculus with 2 samples.

How the data were processed

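NF-E2 p45 is the blood-cell-restricted subunit of the transcription factor NF-E2, which binds DNA as a dimer with a small Maf protein. Its genomic positions were measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse megakaryocytes, the cells that release platelets. Per the labels' protocols, liver cells of C57BL6 fetuses at embryonic day 13.5 were grown with thrombopoietin at 50 ng/ml and taken on day 3. The chromatin was fixed with formaldehyde and sheared by sonication. Libraries were sequenced on an Illumina Genome Analyzer IIx. The series holds 1 library made with an antibody to p45 and 1 input library made without antibody. There are no replicate libraries in either group.

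The data used here are the peaks of the p45 library. Per the submitters' processing notes, coordinates are on mouse build mm9. The deposited peak names show that MACS was the peak caller, and the deposited file's name says that a control was used. That this control was the input library is not given in the sources used here. The aligner, the MACS version, its settings and the treatment of duplicate reads are not given in the sources used here. The deposited list has 5 columns with no header: chromosome, start, end, peak name and 1 score per peak, which is the authors' own value. Peak numbers run from 1 to 1651 without a gap. Tag counts, fold enrichment, false discovery rates and summits are not among these columns. Starts were read as zero-based, as in the BED format, and are printed 1-based.

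The scale of the score was inferred from its values. The lowest score was 50.04. The most frequent scores, 76.44 and 90.96, were fitted as 10 times the negative decimal logarithm of a Poisson tail probability, which gave a background rate of 0.283 tags per scored window. With that rate, 250 of the 1651 peaks (15.1%) lay within 0.03 of a predicted score. This count includes the peaks with the fitted scores, which lie on the steps because of the fit. Of the 1542 peaks with other scores, 141 lay on the steps. The score was read on that scale for the whole list, where 50 stands for a probability of 1 in 100000. The highest score, 3100, was shared by 2 peaks and was treated as a tie. Whether 3100 is an upper limit of the score is not given in the sources used here. The score was used to describe and rank peaks within this list, and the fitted rate to set the steps used in the closing part. The depth of the libraries is unknown, so no interval for single peaks could be given.

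Peaks were counted per chromosome, with exact Clopper-Pearson 95% intervals for shares. Because chromosome lengths of mm9 were not used here, the expected count was taken from the span between the first and the last peak of each chromosome. This choice was added after the data were examined. Counts on chromosomes 1 to 19 and X were compared with it by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 20 chromosomes. Scores on each chromosome were compared with the rest by a two-sided permutation test of the mean rank with 100000 resamples. Adjacent peaks at most 10 kb apart were counted and compared with 1000 random placements on the same chromosomes by a one-sided permutation test. A second background moved every peak by 50 to 500 kb. Runs of peaks were compared with both backgrounds, a test added after the runs were seen. Shares of peaks between classes were compared by a two-sided Fisher's exact test. Score and length were compared by Spearman's rho across peaks with 100000 permutations. Peaks are not independent replicates, so each p-value describes this list against a random arrangement, and intervals cover counting error only. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

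The scripts were tested on simulated data. With 1645 peaks and 1 chromosome given 2 times its share, the density test called that chromosome in 100 of 100 runs, and random placement gave any call in 4 of 100. The neighbour test called 40 planted pairs in 20 of 20 runs and random placements in 0 of 20. That check used random placement as the background, and the second background, of moved peaks, was not simulated. A planted background rate of 0.4 was recovered from 1600 scores, with 300 of 300 planted scores placed on its steps. The correlation test called 4 of 100 sets of 300 unrelated values.

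The peaks to be named were fixed before the data were examined as the 10 with the highest score. Other regions in the text were chosen after their values were seen. Comparisons fixed in advance that need a genome or annotation of mm9 were not run. These were distance to transcription start sites, genomic features, the NF-E2 and other sequence motifs, and gene lists. A class of peaks of nearly the same length was set after the data were examined. Its bounds were 545 to 590 bp at first, and were changed to 540 to under 590 bp after results with the first bounds had been seen. The ratios of the class on chromosomes 11 and X and the correlation without it are given with both. Genes are not named, since the gene table at hand is on GRCm38 and coordinates were not moved between builds. Alternatives that need false discovery rates, fold enrichment or tags were not run either. The alternatives that were run took peaks at or above the median score, autosomes, scores of at least 100, peaks outside the most common length, the list without its 1% highest scores, clustered peaks counted once, other gaps and other backgrounds.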

Results

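The p45 library gave 1651 called peaks, covering 1.16 Mb of the mouse genome. Chromosomes 1 to 19 carried 1605 of them, chromosome X 40, chromosome Y 1 and contigs without a full placement 5. The series asks where NF-E2 p45 sits along the genome of megakaryocytes, and each peak was called in the p45 library against a control. There was 1 p45 library and 1 input library, so no peak has a replicate check and no value carries a spread between replicates. Tag counts were not part of the list, and the depth behind each peak is unknown. The median score was 76.44, with quartiles of 61.97 and 106, and the median length was 648 bp, with quartiles of 556 and 819 bp. Scores of at least 100 were held by 460 peaks, which is 27.9% (95% interval 25.7 to 30.1%, Clopper-Pearson). Only 15 peaks reached 500.

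The strongest p45 peaks lay on chromosomes 11, 1 and X. A 724 bp peak on chromosome 11 from 76804001 to 76804724 and a 689 bp peak on the same chromosome from 104472829 to 104473517 shared the top score of 3100. A 1429 bp peak on chromosome 1 from 166064947 to 166066375 followed with 3053.66. Next came 2 neighbouring peaks on chromosome X. The first, from 7536575 to 7538082, scored 1255.61 over 1508 bp, and the second, from 7538793 to 7540609, scored 1279.27 over 1817 bp. The gap between them was 710 bp. Chromosome 2 held the sixth peak, from 16604443 to 16605061, with a score of 974.48, and the tenth, from 125973367 to 125973940, with 613.11. On chromosome 6 a 585 bp peak from 69466074 to 69466658 scored 808.12, and a 600 bp peak from 125567781 to 125568380 scored 691.32. A 1506 bp peak on chromosome 15 from 103078630 to 103080135 scored 644.61. Which genes, exons or introns lie at these positions was not analysed here. All coordinates are on mm9.

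Over the whole list, peaks of p45 were most dense on chromosome 11 and least dense on chromosome X. Chromosome 11 held 157 peaks, 9.54% of the 1645 on chromosomes 1 to 19 and X (95% interval 8.17 to 11.1%). That was 1.33 peaks per Mb of span, against a median of 0.654 over the 20 chromosomes. The count was 2.01 times the 78.0 expected from its span (95% interval 1.72 to 2.33), with an adjusted exact binomial p of 8.6e-15. Chromosome X held 40 peaks where 103.0 were expected, a ratio of 0.388 (95% interval 0.278 to 0.526), with an adjusted exact binomial p of 6.6e-12. When only scores of at least 100 were kept, the ratio on chromosome X was 0.627 and the adjusted exact binomial p was 0.28. Among peaks from 540 to under 590 bp, a class set after the lengths were seen, its ratio was 0.850 (95% interval 0.544 to 1.26, adjusted exact binomial p = 0.914), and among other lengths 0.224 (95% interval 0.131 to 0.357). Chromosome 19 was not called in the whole list (ratio 1.39, adjusted exact binomial p = 0.0926). It was called at or above the median score, with a ratio of 2.01 (adjusted exact binomial p = 8.1e-04), and at scores of at least 100, with 2.35 (adjusted exact binomial p = 0.00166) against 2.07 on chromosome 11. Chromosome 5 was above its expected count with 124 peaks, a ratio of 1.27 and an adjusted exact p of 0.038. Chromosome 14 was below it with 49 peaks, a ratio of 0.684 and an adjusted exact p of 0.036. The calls for chromosomes 5 and 14 ended when peaks within 50 kb of each other were counted once (adjusted exact binomial p of 0.0953 and 0.0653), at or above the median score (0.305 for both) and at scores of at least 100 (0.475 and 0.295). In the same order, the ratios were 1.25 each time on chromosome 5, and 0.697, 0.697 and 0.60 on chromosome 14. The other 16 chromosomes did not pass the test in the whole list. This test against spans was chosen after the data were seen, and the spans come from the peaks themselves. Spans take no account of gene content or of where reads can be placed, so the ratios are not adjusted for either.

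**Figure D1:**
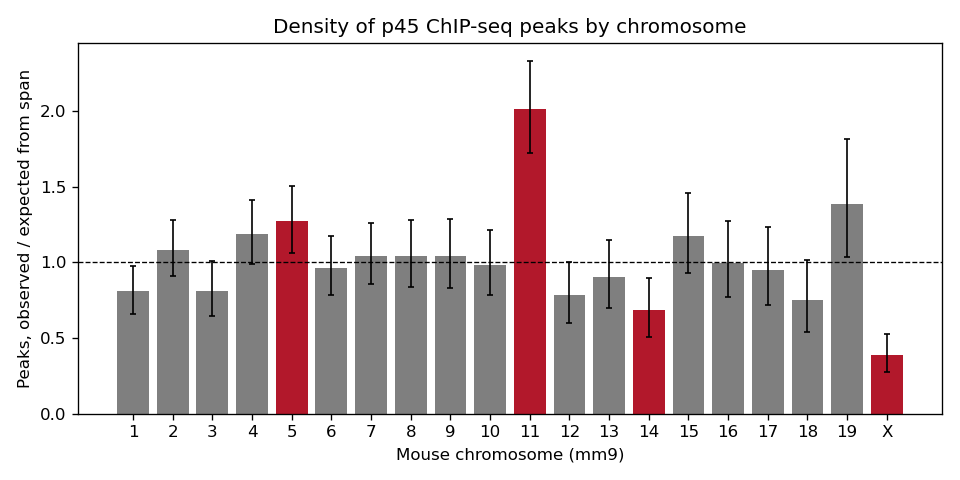
Observed over expected number of p45 peaks (y axis, ratio) for chromosomes 1 to 19 and X of mm9 (x axis), expected counts being taken from the span between the first and last peak. Error bars are exact 95% intervals, red bars have an adjusted exact binomial p under 0.05, and the dashed line marks 1. Chromosome 11 stands at 2.01 and chromosome X at 0.388.

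Peak scores had higher ranks on chromosomes 19 and X than on the rest. The median score was 96.18 on chromosome 19 and 90.8 on chromosome X, against 76.44 in the whole list. The mean rank was at percentile 62.6 on chromosome 19 (adjusted permutation p = 0.028) and at percentile 63.1 on chromosome X (adjusted permutation p = 0.035). Chromosome 11, the densest, had a median score of 76.44 and a mean rank at percentile 50.6 (adjusted permutation p = 0.956). Chromosome 7 had a median score of 68.1 and a mean rank at percentile 43.1, which did not pass after adjustment (permutation p = 0.0125, adjusted 0.083). On chromosome X, 23 of the 40 peaks had lengths from 540 to under 590 bp. Without peaks of that length its mean rank was at percentile 59.5 (unadjusted permutation p = 0.175), and with the bounds of 545 to 590 bp it was at 56.6 (unadjusted permutation p = 0.33). At or above the median score the mean ranks were at percentiles 53.2 on chromosome X (unadjusted permutation p = 0.541) and 57.5 on chromosome 19 (unadjusted permutation p = 0.109). At scores of at least 100 they were at 61.6 on chromosome X (unadjusted permutation p = 0.083) and 50.1 on chromosome 19 (unadjusted permutation p = 0.988).

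Neighbouring p45 peaks were more frequent than random placement gave. In 44 places, adjacent peaks lay at most 10 kb apart, against 12.3 ± 3.4 (SD over 1000 placements), a ratio of 3.56. No placement exceeded 25, and the permutation p of 0.001 was the smallest that 1000 placements can give. When each peak was moved by 50 to 500 kb, which keeps the regional density, 22.3 ± 4.7 pairs were found, a ratio of 1.98 (permutation p = 0.001). With a gap of 50 kb, 131 pairs were found against 102 ± 9.0 among shifted peaks, a ratio of 1.29 (permutation p = 0.002). Runs of at least 3 peaks, each within 50 kb of the next, numbered 14 and held 48 peaks. Random placement gave 2.07 ± 1.45 runs (permutation p = 0.001), and shifted peaks gave 7.58 ± 2.59 (permutation p = 0.018). Chromosome 11, which also held the most peaks, had 4 of these runs, and no expected number was computed for it alone. The fullest run held 6 peaks in 15.6 kb of chromosome 11, from 104382595 to 104398241, with scores from 68.92 to 198.22. It ended 74.6 kb before the peak of score 3100 that starts at 104472829. A run of 4 peaks on chromosome X, from 7510573 to 7553943, held both of the strong peaks described above, with flanking peaks of 103.14 and 163.34. Runs of 4 peaks also lay on chromosome 4 from 128634658 to 128710370, with a highest score of 185.26, and on chromosome 10 from 76662006 to 76688978, with a highest score of 110.72. These runs were singled out after their values were seen. Of the 165 peaks in the top 10% by score, 28 had a neighbour within 50 kb, or 17.0% (95% interval 11.6 to 23.6%). Among the other 1480 the share was 14.3% (95% interval 12.6 to 16.2%), and the difference did not pass a two-sided Fisher's exact test (p = 0.353). With the gap of 10 kb, the ratio to random placement was 4.81 among peaks at or above the median score and 8.03 at scores of at least 100 (permutation p = 0.001 for both), and the difference from 3.56 was not tested. These subsets were not compared with shifted peaks, which lowered the ratio of the whole list from 3.56 to 1.98.

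**Figure D2:**
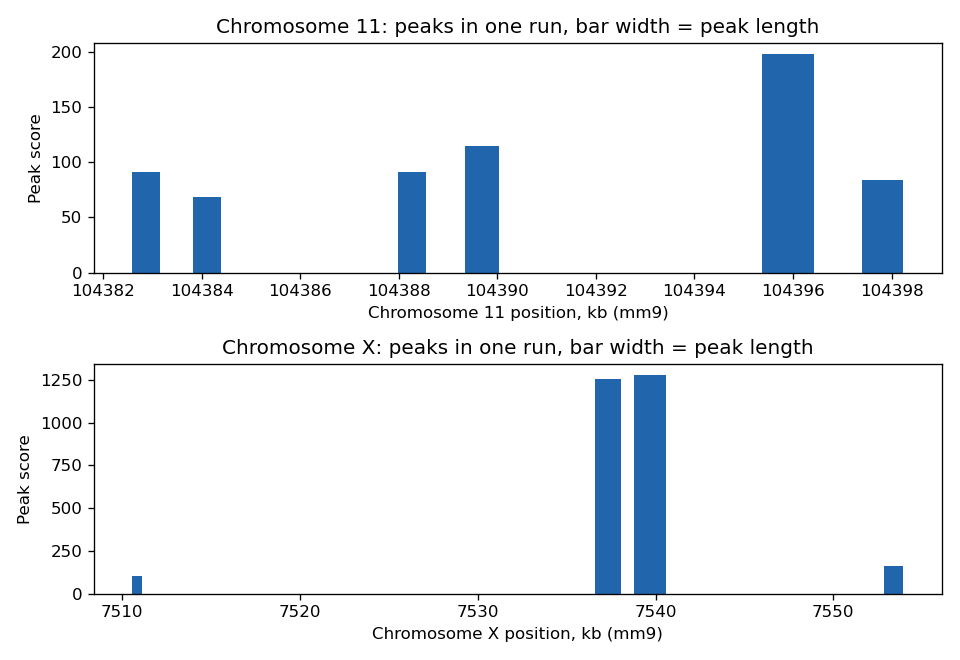
Peak score (y axis) along mm9 position in kb (x axis) in the run of 6 peaks on chromosome 11 and the run of 4 peaks on chromosome X, each bar being 1 peak drawn to its length. Scores run from 68.92 to 198.22 in the first and from 103.14 to 1279.27 in the second.

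Longer p45 peaks were not the stronger ones over the whole list. Spearman's rho between score and length across the 1651 peaks was −0.17, with a permutation p of 1e-05, the smallest that the resamples can give. Peaks scoring from 50 to under 60 had a median length of 750 bp, those from 100 to under 150 had 559 bp, and the 15 peaks of at least 500 had 936 bp. Among the 828 peaks at or above the median score, rho was 0.19 (permutation p = 1e-05), and among the 823 below it rho was −0.10 (permutation p = 0.0027). A single narrow range of lengths was overrepresented: 434 peaks, 26.3% of the list (95% interval 24.2 to 28.5%), measured from 540 to under 590 bp. The 50 bp ranges on either side held 98 and 99 peaks. Its share of the peaks differed with score. It was 10.1% from 50 to under 60, 37.6% from 100 to under 150 and 47.6% from 150 to under 250. From 250 to under 500 it was 46.8%, and among the 15 peaks of at least 500 it was 13.3%. Of the peaks named above by their score, those of 808.12 on chromosome 6 and 613.11 on chromosome 2 fell in this range. This range was set after the lengths were seen. Without the 434 peaks, rho was −0.04 (permutation p = 0.14). The longest peak, 6893 bp on chromosome 11 from 3056458 to 3063350, scored 96.02. Beside it lay a peak of 1094 bp, from 3054821 to 3055914, with a score of 87.67. The next longest in the list, 2669 bp on chromosome 18 from 3008036 to 3010704, scored 60.25. Whether repeated sequence lies at these positions was not analysed here.

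**Figure D3:**
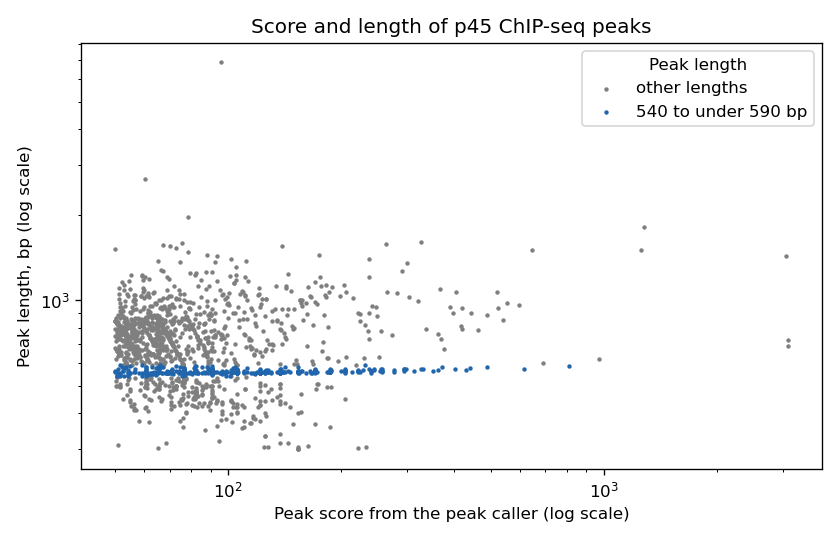
Length in bp (y axis, log scale) against score (x axis, log scale) for the 1651 peaks, each point being 1 peak, with the 434 peaks from 540 to under 590 bp in blue. The blue points form a band that reaches a score of 808.12, while the other peaks spread from 298 to 6893 bp.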

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

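All tests in this part were chosen after the data were seen. Only the outcome of counting clustered peaks once was stated before its value was seen. The tests on length classes, on lengths across score steps and on score steps on chromosome X count as stated after their results. The length class was first 545 to 590 bp, with 425 peaks, and was changed to 540 to under 590 bp after its results were seen.

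Contigs without a full placement, left out of the comparison of chromosomes, held 5 peaks. A peak of 800 bp on 1_random scored 97.49, one of 1972 bp on 9_random scored 78.21 and one of 554 bp on X_random scored 106. The 2 peaks on Un_random scored 56.67 and 54.77. The only peak on chromosome Y, 574 bp long with a score of 204.47, was left out as well.

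The first pattern is the excess of peaks from 540 to under 590 bp: of the 250 peaks whose scores lay on the series of Poisson steps with a rate of 0.283, 201 had such a length. Tags stacked at one or few start positions stay open: median length differed by 7.5 bp between the lowest frequent step and counts of 12 or more, but the class holds most peaks on the steps, so this decides nothing. Positions spread without regard to p45 stay open too. The class was at 1.71 times its expected number on chromosome 11 (interval 1.20 to 2.34, adjusted exact binomial p = 0.0424) and at 1.60 with the first bounds (1.10 to 2.22, 0.222), and more reads from that chromosome would raise such positions as well. Whether duplicate reads were kept is not given in the sources used here, so amplified copies and sharply placed binding were not separated.

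The second pattern is the excess on chromosome 11. Counting peaks within 50 kb of each other once left a ratio of 1.88, which argues against a few crowded regions as the whole cause. More reads from the whole of chromosome 11 would raise every class of peak, and this stays open. On chromosome 11, 13.4% of peaks lay on the steps of the fitted rate, against 14.3% on all autosomes, a difference that was not tested. The excess in the class of 540 to under 590 bp was not called with the first bounds, and the difference in share between classes did not pass a two-sided Fisher's exact test (p = 0.253, and 0.124 with the first bounds), which does not show equal shares. A larger number of p45 sites on this chromosome is a biological alternative, and it was not tested. The expected count rests on span alone, so the gene content of the chromosome was not taken into account.

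The third pattern is the shortage on chromosome X, where 45% of the 40 peaks, or 18, lay on the steps of the fitted rate, against 14.3% on the autosomes (two-sided Fisher's exact p = 4.5e-06). The share on the steps cannot decide whether a lower background caused fewer peaks. On the score scale read here, a lower background alone would not lower any score or remove peaks. By itself it would therefore not give a shortage. Of the 18 peaks on chromosome X, 17 also had lengths from 540 to under 590 bp, so the score steps and the length class are not separate evidence. The sex of the fetuses is not given in the sources used here, so the number of copies of chromosome X is unknown. Fewer reads from the whole of the chromosome cannot be told apart from no change in the length class of 540 to under 590 bp. There the ratio was 0.850 with an interval of 0.544 to 1.26 (0.830, 0.525 to 1.24, with the first bounds). Other lengths had a ratio of 0.224 (0.235), and the classes differed in their share on chromosome X (two-sided Fisher's exact p = 2.7e-05, and 6.8e-05 with the first bounds).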

How the results depend on the processing

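Alternatives based on scores of at least 100, on length, on the 1% highest scores, on clustered peaks counted once, on spans and on shifted peaks were chosen after seeing the data. The list of 1651 peaks fell to 828 at or above the median score and to 460 at scores of at least 100. The share of peaks on chromosome 11 stayed between 8.91 and 10.2% under its 7 alternatives, inside its own interval. Its ratio of 2.01 kept its call under each of the 7 alternatives run for it, from 1.88 to 2.16. The ratio on chromosome X kept its call under 6 of 7 alternatives, and at scores of at least 100 it was 0.627 with an adjusted exact p of 0.28. The number of chromosomes that passed was 4, and it was 2 with clustered peaks counted once (11 and X) and 2 at scores of at least 100 (11 and 19); the cause was not tested. Chromosome 19 was also called at or above the median score, and chromosome 3 was called, at 0.658, without the peaks from 540 to under 590 bp. The excess of neighbouring peaks kept its call under each of its 11 alternatives. Ratios ran from 1.29 (50 kb gap, shifted peaks) to 8.03 (scores of at least 100, random placement). Among peaks from 540 to under 590 bp alone, the 50 kb gap against shifted peaks gave a permutation p of 0.114. The correlation of score and length depended on the peaks taken. It was −0.17 in the full list, 0.186 at or above the median score, 0.240 at scores of at least 100 and −0.042 without the peaks from 540 to under 590 bp (−0.036 with the first bounds, 545 to 590 bp). Chromosomes 5 and 14 lost their calls in 5 of 7 alternatives. In those 5, the ratios ran from 1.248 to 1.285 on chromosome 5, against 1.273 in the whole list. On chromosome 14 they ran from 0.6015 to 0.6971, against 0.6839. Alternatives on false discovery rates, fold enrichment, tags, summits and genes were not run. Depth limits all of this: with no tag counts and no replicate library, an absent peak was not separated from one below the caller's limit.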

Other observations

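The score steps give a view of depth that the list does not state, in a test chosen after the data were seen. With the rate fitted on the scores of 76.44 and 90.96 alone, 141 of the 1542 peaks with other scores lay within 0.03 of a predicted step. Of these, 1 peak at 90.97 lay on a fitted step, which leaves 140 of 1541. Moving the steps by 52 other offsets gave 6.2 on average and 26 at most. Other rates from 0.02 to 0.278 placed up to 34 of these peaks on their steps, and rates from 0.289 to 5.00 placed up to 63. Rates nearer to the fitted one were left out of this count. If the score is the chance of more tags than were counted, the 66 peaks at 76.44 had 6 tags and the highest step occupied, at 489.74, had 29. Only 1 peak lay on the step of 5 tags, at 62.49, although that score is above the lowest in the list.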
